A study of Homo sapiens with 17 samples.

How the data were processed

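Chromatin immunoprecipitation with sequencing was done by the authors for RAD21 and H3K27ac in atrial cardiomyocytes at day 20 of differentiation from WTC11 cells, with WT, TBX5in/+ (heterozygous) and TBX5in/del (null) genotypes. The 17 libraries were 9 for RAD21, 6 for the H3K27ac differential set and 2 for a separate WT H3K27ac set. Per the labels each replicate was a pooled 6-well plate and 1 biological replicate. Groups were taken from the labels, and the replicate number was not used to pair libraries, since correlations of peak deviations between libraries of the same number were near 0.

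Per the labels the authors aligned reads to hg38 and used Bowtie2, SAMtools, bedtools and MACS2, with no versions stated. The deposited peak files hold, per library, a peak score, a fold enrichment (a ratio of signal over background) and -log10 values of the p-value and the q-value of each peak. The highest q-value of any deposited peak was 0.1. The deposited differential tables hold a mean normalised signal per region (coverage averaged over the libraries), a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value. The authors' merged RAD21 files were rebuilt exactly as the bases covered in at least 2 of 3 libraries, with 47150, 48203 and 42939 regions. The 79619 tested H3K27ac regions were rebuilt as the merged union of the replicate intersections per genotype, and the 4 deposited lists of changed regions as those with an adjusted p under 0.05 and a log2 fold change beyond 0.6. In the table for heterozygous libraries, 20067 regions of low signal (mean up to 42.5) had no adjusted p and were not called, and 59552 had one. Counts per library were not used here, so that no model was fitted and no replicate was left out for the differential calls. The sequencing depth was not analysed here, and peak numbers per library, from 43137 to 61256 for RAD21 and from 57075 to 83311 for H3K27ac, stand in for it.

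The contrast of null against heterozygous was derived from the deposited values. Genotype means and a dispersion per region were solved from the mean signal, the log2 fold changes and the standard errors under equal depth, the dispersions from the 2 contrasts had a Spearman correlation of 1.000 across regions, and a normal test with Benjamini-Hochberg adjustment was applied. Tested on simulated data with 400 changed regions among 20000, this contrast called 400 of them and 18 others. This checked the calculation. Sensitivity to changes of the size and dispersion found in the data was not tested. The effect of the shared WT libraries was estimated from 20 simulations with these means and dispersions. Regions were tied to the protein-coding gene whose body they overlap (the shortest), or else the nearest body within 100 kb. The gene table used here gives no strand, so that distances to transcription start sites were replaced by distances to either gene end, with 2 kb as the window. Sequence motifs were not analysed here.

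Named genes were, per H3K27ac contrast and direction, the 12 with the largest deposited change among called regions above the median signal of 99.5, the strongest members of each list, and the 5 strongest RAD21 regions per class, and some of these are not reported here. The 24 gene lists, the rule for named genes and the tests were fixed before the data were examined, apart from those named as chosen later. For each list, genes with a called region and the median over genes of the mean log2 fold change were compared with 10000 random lists drawn within 10 bins of regions per gene, two-sided, with Benjamini-Hochberg adjustment over the lists of a contrast. The smallest p that these lists can give is 0.0002. Tested on simulated lists, 9 of 200 random lists of 25 genes had a p under 0.05 and 20 of 20 lists with planted genes did. Location and overlap counts were compared by two-sided Fisher's exact tests, and width-matched odds ratios by the Mantel-Haenszel method over 10 width bins.

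RAD21 peaks of all 9 libraries were merged when they shared 1 bp. Library values were compared by two-sided exact permutation tests, and similarity by the Jaccard index of covered bases over all 280 partitions of the 9 libraries. Of 200 regions planted in copies of 1 library, 200 were counted. The copies had no replicate noise, so that this checked the counting alone. Overlaps matched those of bedtools 2.31.1. Alternatives were other thresholds for p, fold and peaks, regions above the median signal, centred fold changes, other gene distances, equal peak numbers, other overlaps, and leaving out each replicate. Comparisons of 3 RAD21 libraries with 3, or of fewer, cannot give a p under 0.05, so that their alternatives could not cross this threshold. The overlap alternative for regions called in both contrasts could not differ either, since both contrasts use the same regions. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.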

Results

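Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, and binding of the cohesin subunit RAD21 were compared between 3 TBX5 genotypes of atrial cardiomyocytes at day 20 of differentiation from the induced pluripotent stem cell line WTC11. TBX5 is a T-box transcription factor of the atria and the left ventricle. The genotypes were WT, heterozygous (TBX5in/+) and null (TBX5in/del), with 3 RAD21 libraries and 2 H3K27ac libraries each, and 2 further WT H3K27ac libraries formed a separate set. H3K27ac fold changes, their standard errors (SE) and adjusted p-values below were read from the authors' deposited tables of 79619 regions on the genome build hg38. A region was called when its adjusted p was under 0.05 and its log2 fold change was at least 0.6 in either direction of change.

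The TBX5 locus itself lost H3K27ac with dose. The authors' deposited tables held 20 regions within 100 kb of TBX5 (chromosome 12, 114353911 to 114408442), of which 6 overlapped the gene body. In the null contrast 16 of the 20 were called lower and 1 higher, and in the heterozygous contrast 5 were called lower and 0 higher. The region from 114441428 to 114452242, which lies 33.0 kb outside the gene, had deposited log2 fold changes of -5.51 ± 0.25 (SE) in null and -0.80 ± 0.23 in heterozygous libraries, and a peak was present in both WT, both heterozygous and neither null library. The broad region from 114390640 to 114418621, which covers one end of TBX5, had deposited values of -3.13 ± 0.27 in null and -0.89 ± 0.27 in heterozygous libraries. The 3 regions farthest on the other side, between 114266104 and 114302098, had deposited null values from 0.63 to 1.27, and the called one was at 114287567 to 114289045.

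**Figure D1:**
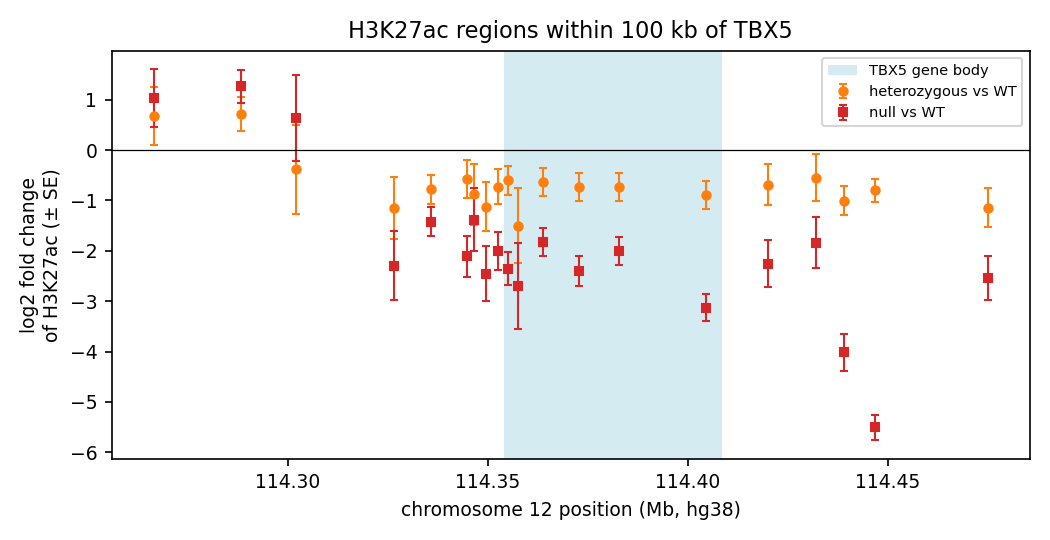
Deposited log2 fold change of H3K27ac (vertical axis, ± SE) against position on chromosome 12 (horizontal axis, Mb, hg38) for the 20 regions within 100 kb of TBX5, in heterozygous and null libraries. In null libraries 16 of the 20 regions were called lower, and the lowest value was -5.51.

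Heterozygous cells lost H3K27ac most at genes of the imprinted 15q11 domain and at several zinc finger and histone genes. In the authors' deposited table of heterozygous against WT, the region at SNURF, at the shared promoter of SNURF and SNRPN (chromosome 15, 24954468 to 24958096), had a log2 fold change of -7.02 ± 0.32, and its deposited value in null was -0.36 ± 0.22. A second region at SNRPN had deposited values of -5.16 ± 0.28 in heterozygous and -0.96 ± 0.27 in null libraries. Among the other genes with the lowest deposited heterozygous values at their assigned regions, ZNF880 (-5.46), MBD3L1 (-4.18) and TRA2A (-2.84) were also called lower in null. H4C6, a histone H4 gene, had deposited values of -5.03 ± 0.38 in heterozygous and -1.65 ± 0.28 in null libraries, and CCDC169 had -3.75 and -0.71, with both called lower in both contrasts. ZNF300 (-4.91 ± 0.32), ZNF680 (-3.19 ± 0.36), GOLGA6L2 (-2.61 ± 0.32) and NDN (-2.58 ± 0.36) were called lower in the deposited heterozygous table and not in the null table. Neither separate WT library had a peak at the regions assigned to GOLGA6L2 and NDN, while both had one at ZNF300, ZNF680 and SNURF. The genes whose assigned regions had the highest deposited heterozygous values were ZNF559 (3.25 ± 0.37), TAF9B (3.20 ± 0.32), HS2ST1 (2.28), NELL1 (2.19), LCLAT1 (2.06), COPRS (2.01), SPANXB1 (1.98), GORASP2 (1.98), ALOX5AP (1.92), IL15 (1.84), MTERF4 (1.83) and LRRC1 (1.82). Of these 12 genes 10 were called higher in null as well, with LCLAT1 (0.59) and GORASP2 (0.52) as the exceptions. The regions at ZNF559 and TAF9B had a peak in both separate WT libraries and in neither WT library of the differential set. In all, 2890 regions were called lower and 4496 higher in heterozygous libraries, 9.28% of all 79619 regions, with median deposited log2 fold changes of -0.91 and 1.00. Only 59552 regions had an adjusted p in this contrast, against all 79619 in the null contrast, so that the 2 shares are not on the same footing. At an adjusted p under 0.01 these counts were 760 and 1818, and with fold changes centred on their median 1937 and 5662, so that the share of losses depended on the scaling.

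**Figure D2:**
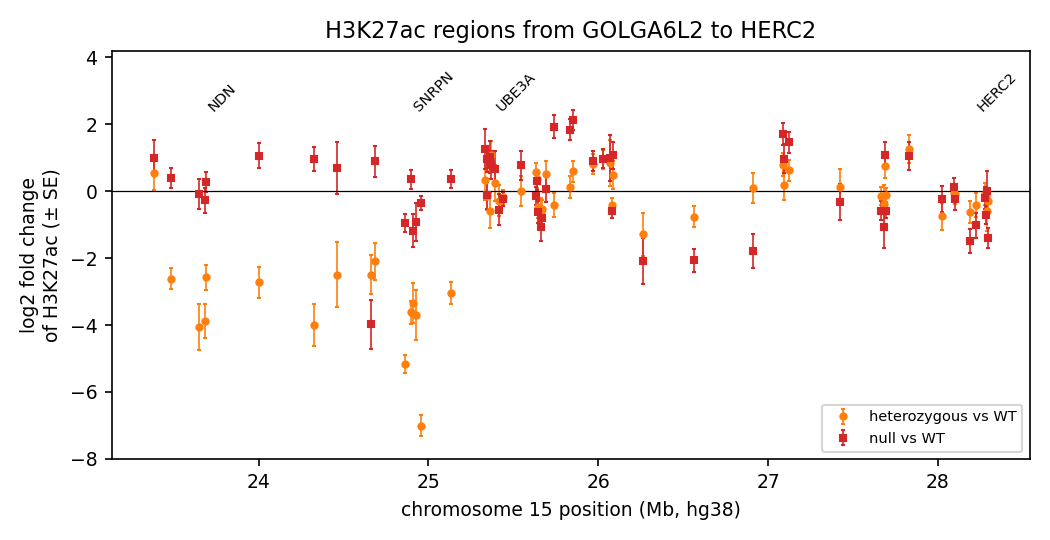
Deposited log2 fold change of H3K27ac (vertical axis, ± SE) against position on chromosome 15 (horizontal axis, Mb, hg38) from GOLGA6L2 to HERC2, in heterozygous and null libraries. The lowest heterozygous value, -7.02, was at SNURF.

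Null cells lost H3K27ac at TBX5 and at heart muscle genes, and gained it at matrix genes. The lowest deposited null values, at regions in or within 100 kb of the genes, after ZNF880 (-6.11 ± 1.06), included those of GIMAP6 (-5.67 ± 0.33), TBX5, LYPLAL1 (-5.35 ± 0.52), FAM241B (-5.23 ± 0.28), ADAM11 (-5.06 ± 0.30), MRC1 (-4.96 ± 0.27), FHL2 (-4.84 ± 0.36), PPP1R14C (-4.83 ± 0.26), CARD10 (-4.82 ± 0.39) and WNT2 (-4.82 ± 0.27). FHL2 encodes a LIM-domain protein of heart muscle and WNT2 a secreted signalling protein. The highest deposited null values were those of ZNF559 (3.38 ± 0.37), the kinase gene PRKG1 (3.21 ± 0.31), the forkhead factor gene FOXC1 (3.21 ± 0.32), PADI2 (3.16 ± 0.26), KCTD14 (3.13 ± 0.25), ZNF235 (3.02 ± 0.30), GMDS (2.95 ± 0.25), TAF9B (2.95 ± 0.32), PRIM2 (2.90 ± 0.32), ROS1 (2.90 ± 0.33), ATG4D (2.90 ± 0.34) and FBN1 (2.89 ± 0.27), which encodes fibrillin of the extracellular matrix. As given above, both separate WT libraries had a peak at ZNF559 and TAF9B, so that these values may not reflect a gain over WT cells. In all, 18155 regions were called lower and 16197 higher in the deposited null table, 43.1% of the regions, with median log2 fold changes of -1.44 and 1.21. Log2 fold changes beyond 2 were found in 4301 of the lower and 985 of the higher regions. A peak in both WT and neither null library was present for 32.0% of the lower regions, and the reverse for 44.7% of the higher regions.

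Heterozygous cells changed in the same direction as null cells, and by less, at most regions called in null. Over the 34352 regions called in null libraries, the heterozygous value had the sign of the null value in 96.0% and lay between 0 and the null value in 92.3%. The median ratio of heterozygous to null log2 fold change was 0.40 in the lower regions (quartiles 0.28 and 0.54) and 0.51 in the higher regions (quartiles 0.29 and 0.74), and 0.44 in all. Of the regions called lower in heterozygous libraries 94.8% were also called lower in null, and of those called higher 91.3% were also called higher. Both contrasts used the same 2 WT libraries, which ties their values together. In simulated data with the deposited dispersions, null changes as observed and no heterozygous change, these same WT libraries gave a median ratio of 0.05, and the mean number of regions called lower in both was 0.15. The simulation drew noise for each region on its own, so that it cannot show a shift common to both WT libraries. Choosing regions by their null call also favours ratios under 1. The observed numbers called in both were 2740 lower and 4106 higher, against 740 and 1070 for independent lists. A contrast of null against heterozygous derived from the deposited values called 7763 regions lower and 5048 higher. It called null below heterozygous at 41.9% of the regions lower in null, and null above heterozygous at 28.1% of those higher in null. Among the 2740 lower and 4106 higher regions called in both contrasts, this held for 1716 and 630.

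**Figure D3:**
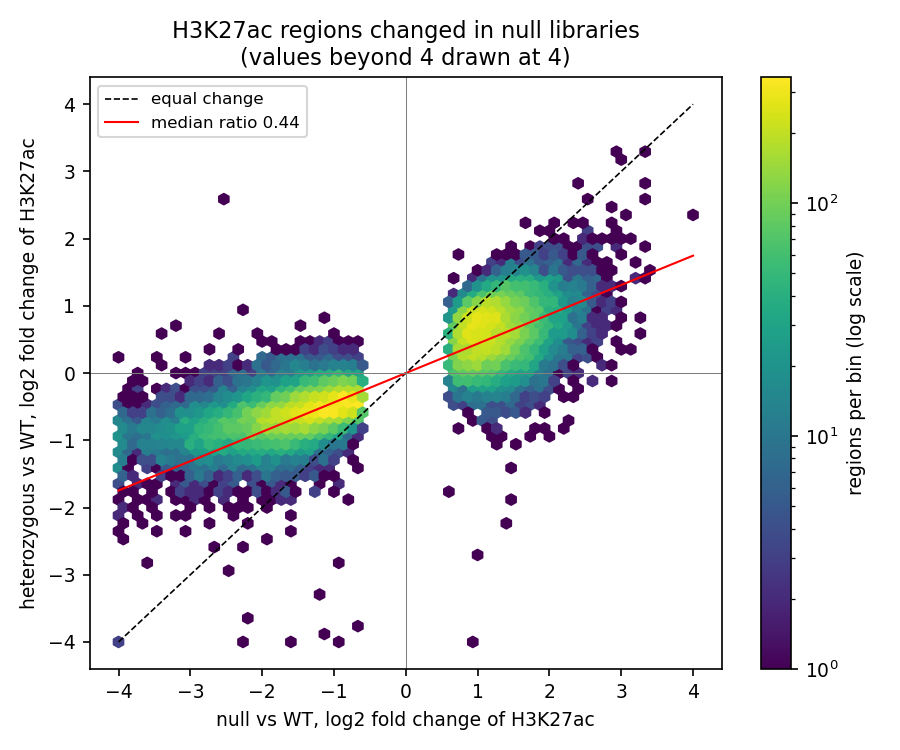
Deposited log2 fold change of H3K27ac in heterozygous (vertical axis) against null libraries (horizontal axis), both against WT, for the 34352 regions called in null libraries, coloured by the number of regions per bin on a log scale. The solid line has the median ratio of 0.44 and the dashed line marks equal change.

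Heart muscle genes lost H3K27ac as groups. Each region was assigned to a protein-coding gene within 100 kb, and for lists of genes fixed before the data were examined the median over genes of the mean log2 fold change was compared with 10000 random lists matched on the number of regions per gene. All 28 sarcomere genes with regions had at least 1 region called lower in null libraries (16.1 in random lists on average, permutation with adjusted p = 0.0048), and 4 of them also had a region called higher. Their median was -1.46 in null and -0.51 in heterozygous libraries. Deposited null values were -2.88 ± 0.21 at MYL3, -2.91 ± 0.23 at TCAP and -2.85 ± 0.26 at LMOD2. Of 19 atrial identity genes 17 had a region called lower in null (permutation with adjusted p = 0.0326, and 0.072 with genes within 20 kb), and the median was -1.61. Deposited null values were -3.92 ± 0.20 at the calcium channel gene CACNA1G and -2.40 ± 0.21 at ADM. Cardiac transcription factor genes had a null median of -0.99, and 25 of 29 had a region called lower, which did not pass after adjustment (permutation with adjusted p = 0.131) but did with genes within 20 kb (24 of 29, 0.037). In heterozygous libraries 18 of 29 had one (6.43 in random lists, permutation with adjusted p = 0.0048). Deposited null values in this list were -3.94 ± 0.27 at IRX4, a ventricular factor gene, and -3.54 ± 0.27 near NKX2-5. Genes at atrial fibrillation loci had a region called lower in 27 of 32 cases in null (20.2 in random lists, permutation with adjusted p = 0.0494) and in 17 of 32 in heterozygous libraries (6.36 in random lists, adjusted p = 0.0048).

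The medians of further heart gene groups moved in the same direction, while several of their gene counts did not pass. Fatty acid and mitochondrial genes had a null median of -0.94, and 19 of 24 had a region called lower (11.8 in random lists, permutation with adjusted p = 0.0326). Deposited null values were -3.22 ± 0.31 at PPARGC1A, a coactivator of mitochondrial biogenesis, and -2.44 ± 0.26 at FABP3. Conduction and calcium handling genes had a null median of -0.85 and a heterozygous median of -0.36. Deposited null values were -3.24 ± 0.26 at the pacemaker channel gene HCN4 and -3.47 ± 0.30 at CACNB2. The null median was -0.89 for ventricular identity genes and -0.46 for congenital heart disease genes (permutation, adjusted p of the medians 0.000533 and 0.0132). Genes with a region called lower in null were 28 of 33 for conduction, 12 of 18 for ventricular identity and 21 of 32 for congenital heart disease, and these counts passed only with regions near gene ends (permutation with adjusted p 0.129, 0.618 and 1 for all regions). In heterozygous libraries 16 of 33 conduction genes and 11 of 24 fatty acid genes had one, and these counts passed with all regions (permutation with adjusted p 0.0115 and 0.0064) but not near gene ends. Within these lists GJA1, a gap junction gene, rose, with a deposited value of 1.69 ± 0.21 in null and 1.03 ± 0.21 in heterozygous libraries. The skeletal muscle list, which holds DES, CKM and ACTA1 that heart muscle also expresses, had the lowest null median of -1.73. Natriuretic peptide and fetal stress genes had a null median of -0.52 that did not pass (permutation with adjusted p = 0.144), although the deposited null values were -3.99 ± 0.29 near NPPB and -2.96 ± 0.32 at NPPA.

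Matrix and epicardial genes gained H3K27ac. Of 23 fibroblast and matrix genes 21 had a region called higher in null (14.0 in random lists, permutation with adjusted p = 0.0096), 8 had a region called lower, and the median was 0.65 in null and 0.32 in heterozygous libraries. Deposited null values were 2.09 ± 0.24 near SPARC, 2.60 ± 0.28 at the cross-linking enzyme gene LOX, 2.11 ± 0.24 near COL5A1 and 1.69 ± 0.26 at COL3A1, while a region at COL6A2 had -2.20 ± 0.21. Epicardial genes had a median of 1.01 in null and 0.55 in heterozygous libraries (permutation with adjusted p 0.000533 and 0.0008). In null 10 of 15 had a region called higher, which did not pass, while in heterozygous libraries 8 of 15 did (permutation with adjusted p 0.131 and 0.0072). Their deposited null values included 2.72 ± 0.23 near ITLN1, 2.27 ± 0.30 near BNC1 and 1.85 ± 0.30 at the retinoic acid enzyme gene ALDH1A2, while a region near WT1 had -2.90 ± 0.39. The endoderm list had a null median of 0.58 (permutation with adjusted p = 0.0132), from 5 genes with regions called higher and 3 with regions called lower among 15. The sign of this median depended on the regions used, since with regions near gene ends alone it was -1.22 over 5 genes (permutation with adjusted p = 0.0228). The endoderm members included GATA4 (deposited null value -2.76 ± 0.24), which the heart also expresses. No difference from random lists passed in null libraries for endothelium (median 0.28), the retinoic acid pathway (0.23), early response genes (0.23), WNT, BMP, NOTCH and TGF-beta genes (-0.01), pluripotency (-0.01), cohesin and CTCF (-0.07), neural genes (-0.13), cell cycle (-0.19), smooth muscle (-0.39) or hypoxia and glycolysis (-0.47), nor for the ribosomal protein genes used as a reference (-0.23). Some of these medians passed under other ways of assigning regions to genes, among them smooth muscle, hypoxia and endothelium. Over 24 lists, 22 of 48 medians and 17 of 96 gene counts passed after adjustment. With p-values adjusted over the list alone, 166 sarcomere regions were called lower in null libraries against 156 with those over all regions tested, and 93 fibroblast and matrix regions were called higher against 89.

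**Figure D4:**
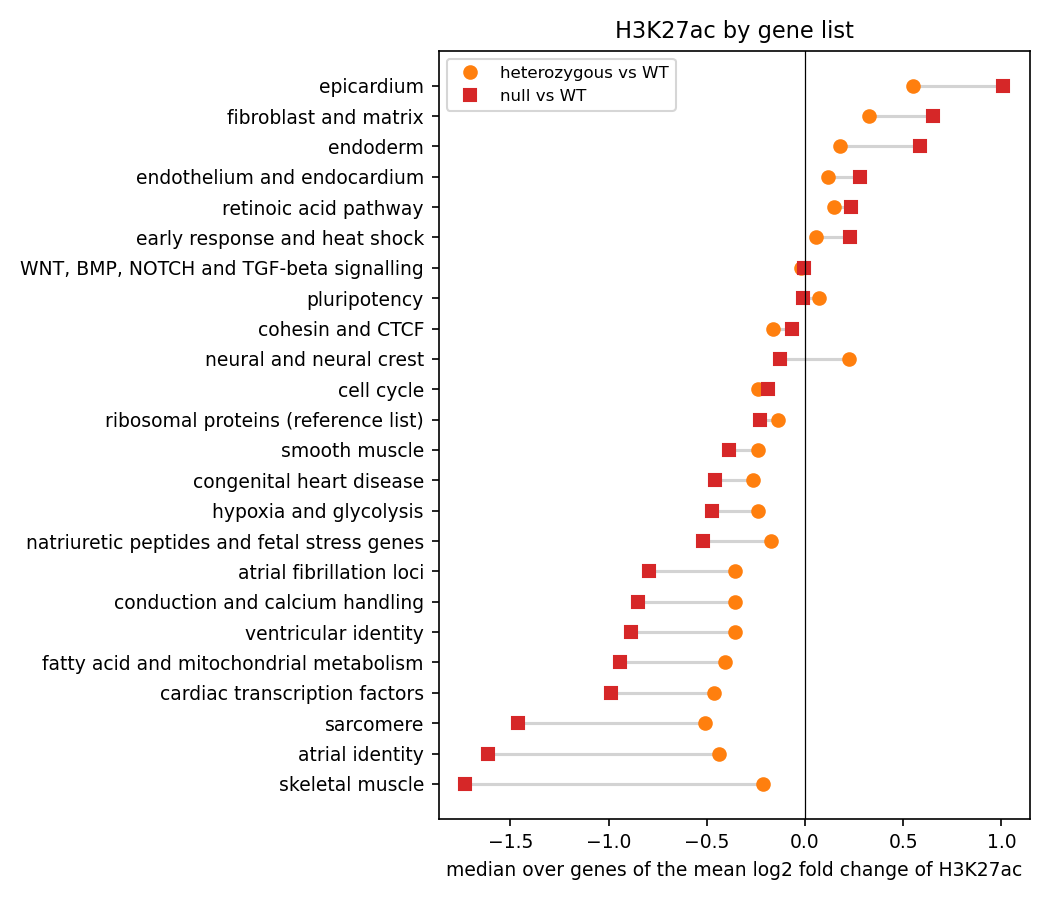
Median over genes of the mean deposited log2 fold change of H3K27ac (horizontal axis) for 24 gene lists (vertical axis) in heterozygous (circles) and null libraries (squares). Null medians ran from -1.73 for skeletal muscle and -1.61 for atrial identity to 1.01 for epicardium.

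Gains and losses lay at different kinds of sites. Regions called higher in null libraries lay within 2 kb of an end of a protein-coding gene in 9.07% of cases, against 21.6% of regions not called, and outside genes in 42.2% against 26.5% (Fisher's exact test, p = 8.54e-293 for the latter). Regions called lower in null lay near a gene end in 20.2%. Regions called lower in heterozygous libraries were near a gene end in 30.8%, against 18.9% of regions not called (Fisher's exact test, p = 1.72e-50), and those called higher in 7.72% (p = 2.94e-95). Here and below, regions not called in heterozygous libraries include the 20067 of low signal without an adjusted p. Regions called lower and higher in heterozygous libraries were also wider (medians 1928.5 and 2005.5 bp, against 1122 bp for all regions). Widths were not matched for location. Regions are neighbours along chromosomes and are not independent, so that these p-values overstate the evidence.

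The separate pair of WT libraries, which did not enter the deposited tables, had peaks in both libraries at 77.4% of the regions called lower in null and at 56.5% of those called higher, with an odds ratio of 2.63. For the heterozygous contrast these shares were 83.9% and 72.2%, with an odds ratio of 2.00 (Fisher's exact test, p = 4.24e-32). The number of H3K27ac peaks per library was 61978 ± 6933 (SD, n = 2) in WT, 73764 ± 2978 in heterozygous, 78258 ± 3627 in null and 78506 ± 6796 in separate WT libraries. The null minus WT difference of 16280 peaks became 8813 without replicate 1 and 23747 without replicate 2, and was described without a test, since 2 libraries against 2 cannot reach a p under 0.05.

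RAD21 sites were in part shared by all libraries and in part found in a single one. Peaks of the 9 libraries merged to 95915 regions, of which 30419 (31.7%) were present in every library and 35218 (36.7%) in 1 library. Peaks per library numbered 49817 ± 6059 (SD, n = 3) in WT, 53258 ± 7017 in heterozygous and 46594 ± 2097 in null libraries, and the differences from WT were within this spread (two-sided exact permutation p = 0.6 and 0.5, smallest possible 0.1). The Jaccard index of covered bases was 0.542 within genotypes and 0.527 between them (exact permutation over 280 partitions, p = 0.0643). The difference of 0.0141 became 0.00192 without replicate 2, and it passed with the same number of peaks taken from each library (0.0162, exact permutation p = 0.0179).

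RAD21 regions found in all 3 libraries of one genotype and none of another numbered 738 for WT and not null, 336 for null and not WT, 236 for WT and not heterozygous, and 487 for heterozygous and not WT. The strongest of the WT and not null regions with an assigned gene lay in SNTG1 (chromosome 8, 50214864 to 50215290), near RBM19 (chromosome 12, 114025782 to 114026397), in LSS, near SAMD11 and near GBP1, with median fold enrichments of 8.38, 8.34, 8.04, 7.86 and 7.80, and 4 of these 5 were present in all 3 heterozygous libraries. At the RBM19 and GBP1 sites the deposited H3K27ac values in null were -1.58 and -2.25. The strongest null and not WT regions with an assigned gene lay near CXCL1, in PARD3 and in ANKFN1 (fold enrichments 5.42, 5.29 and 5.24), and those of heterozygous and not WT in NFIC, near SETD4 and in RGL1 (5.16, 4.96 and 4.83). WT and not heterozygous regions lay near RASGRP1 and in LTBP1, WDR97 and MEGF9 (6.59, 6.26, 6.04 and 6.03). The counts rose when a replicate was left out, since 2 libraries then had to agree in place of 3.

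RAD21 occupancy at changed H3K27ac regions was described per library, and no difference between genotypes passed. At regions with lower H3K27ac in null libraries, the share with a RAD21 peak relative to that of regions not called was 1.24 ± 0.25 (SD, n = 3) in WT, 0.983 ± 0.053 in heterozygous and 0.852 ± 0.013 in null RAD21 libraries. The null minus WT difference was -0.392 (two-sided exact permutation p = 0.1, the smallest possible with 3 against 3). At regions with higher H3K27ac in null the ratio was 0.564 ± 0.046 in WT, 0.808 ± 0.065 in heterozygous and 0.782 ± 0.058 in null libraries, and the differences from WT were 0.244 for heterozygous and 0.218 for null (exact permutation p = 0.1 for each, the smallest possible). The heterozygous minus WT difference at the lower regions was -0.261 (exact permutation p = 0.3), and it was -0.119 without replicate 1 and -0.393 without replicate 3.

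**Figure D5:**
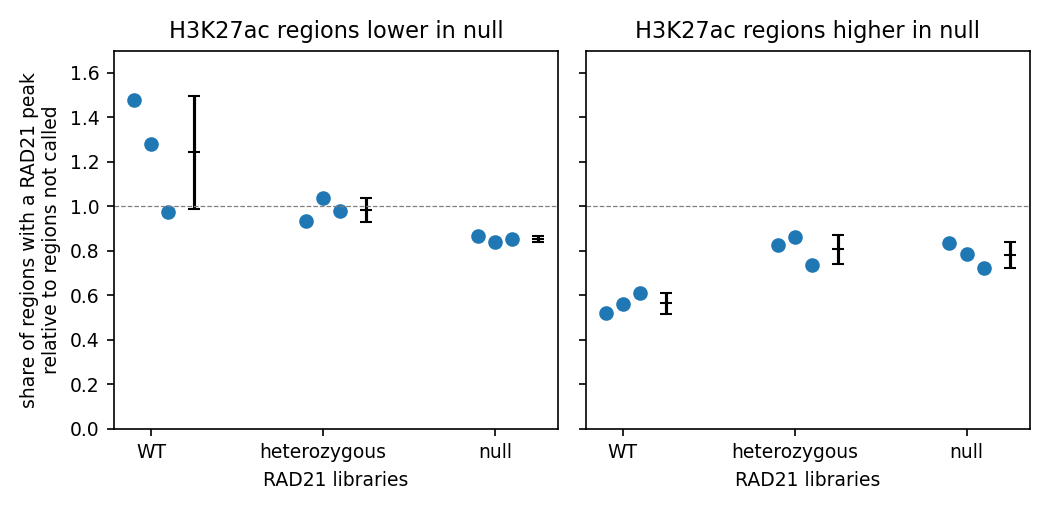
Share of H3K27ac regions with a RAD21 peak divided by the share of regions not called (vertical axis) for each RAD21 library by genotype (horizontal axis), at regions lower (left) and higher (right) in null. Points are libraries and bars are mean ± SD (n = 3), and at lower regions the mean fell from 1.24 in WT to 0.852 in null.

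Over WT and mutant libraries together, cohesin was less common at gained H3K27ac regions. A RAD21 region present in at least 2 of 3 libraries of either genotype overlapped 18.8% of regions called higher in null, against 27.3% of regions not called (Fisher's exact test, odds ratio 0.616, p = 4.2e-106) and 35.3% of such regions of the same width. Regions called higher in heterozygous libraries had RAD21 in 22.3%, against 27.9% of regions not called and 42.3% at the same width. Per library, the share at these regions relative to all regions not called was 0.525 ± 0.113 (SD, n = 3) in WT, 0.936 ± 0.208 in heterozygous and 1.02 ± 0.117 in null libraries. In this comparison the lower share stood in the WT libraries, but the differences from WT of 0.411 and 0.499 did not pass (exact permutation p = 0.1 for each, the smallest possible). With the same number of peaks from each library the means were 0.468 ± 0.157 in WT and 0.762 ± 0.227 in heterozygous libraries (exact permutation p = 0.2). Regions called lower in heterozygous libraries had RAD21 more often, in 50.2% against 27.9% (Fisher's exact test, odds ratio 2.60, p = 9.45e-135), and against 41.2% at the same width. For RAD21 in 3 of 3 libraries the shares were closer, 35.4% against 32.6% at the same width (Mantel-Haenszel odds ratio 1.15). Per library, the share relative to regions not called was 1.92 ± 0.26 (SD, n = 3) in WT, 1.56 ± 0.043 in heterozygous and 1.47 ± 0.050 in null libraries. The differences from WT did not pass (exact permutation p = 0.1 for each, the smallest possible). For regions called lower in null the share was 32.7%, and the direction depended on the comparison, with an odds ratio of 1.30 against all regions not called and 0.912 against those of the same width.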

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

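The test from UBE3A to HERC2, the 2 tests of differences between lists of other cell types and the ratio bounds for changes of about equal size were chosen after results were seen, the bounds of the 15q11 segment were taken from the data, and the other tests here were chosen before. A difference between the 2 genotypes was tested with the derived contrast of null against heterozygous. It singled out 34 regions called lower in heterozygous and not in null libraries with null above heterozygous, 27 regions called higher in heterozygous and not in null libraries with null below heterozygous, and, among these, 7 regions called in opposite directions.

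Of the 34 regions, 8 lay in a segment of 1.65 Mb of 15q11 (chromosome 15, 23483175 to 25135436) that holds the paternally expressed genes MAGEL2, NDN, SNRPN and SNURF. Over its 15 tested regions the median log2 fold change was -3.35 in heterozygous and 0.28 in null libraries, and 14 were higher in null than in heterozygous libraries. Both separate WT libraries had a peak at the SNURF region, and neither had one at the regions assigned to GOLGA6L2, MAGEL2 and NDN. At those genes the 2 WT sets thus differed as well, and the change cannot be told apart from variation between WT sets. Deletion of both copies is argued against, since 100% of the 6 RAD21 regions found in WT there had a peak in at least 2 heterozygous libraries (88.9% genome-wide). Loss of a copy of the whole interval up to HERC2 is argued against by a median of -0.0745 (quartiles -0.41 and 0.56) over 43 regions from UBE3A to HERC2, and a change at imprinted genes in general by the 12 of 28 other imprinted genes with a difference between null and heterozygous libraries, as many as in 0.737 of random lists. A deletion or silencing of the active copy alone stays open and was not tested, and each genotype may stand for a cell clone of its own, which the design cannot separate from TBX5 dose.

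The 7 regions called in opposite directions included 1 near RTL1, an imprinted gene of 14q32, with deposited log2 fold changes of -1.90 in heterozygous and 1.45 in null libraries, 1 near NBPF15 (-1.78 and 0.62), and those in PRDM6 (-0.88 and 0.77) and PCYT1A (0.79 and -1.19), and 2 lay in the 15q11 segment. The largest opposite change, 2.60 in heterozygous and -2.58 in null, was at a region of chromosome 13 (54572089 to 54573152) with no gene within 100 kb. Other regions lower in heterozygous libraries alone lay in AHNAK (-2.79 and 0.35), LRRC61 (-2.48 and 0.52) and ZNF680 (-3.19 and -0.36). Among the 27 regions higher in heterozygous libraries alone were those at HSPA1A (1.52 and -0.25), 6961 bp from GLYAT (1.72 and 0.27) and 83946 bp from NOG (0.97 and -0.06).

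Markers of heart muscle fell and those of epicardium and fibroblasts rose in null libraries, which a lower share of cardiomyocytes could bring about. The tests below ask only if the markers of all other cell types rose alike. A lower share of cardiomyocytes need not raise markers of cell types that the cultures lack, so these tests cannot decide on it. The lowest list median of another cell type was at percentile 0 of random lists, but this was the skeletal muscle list, whose members DES, CKM and ACTA1 heart muscle expresses, so that this bound was a poor one. Without that list the lowest was smooth muscle at 9.5. Smooth muscle was at 1.21 with genes within 20 kb and 0.74 with regions near gene ends, below the bound of 2.5. Near gene ends the endoderm list lay lower still, although its median was 0.58 with all regions. This argues against a rise of all other types alike, but the smooth muscle list holds DES, ACTA2, CNN1 and TAGLN, which immature cardiomyocytes also express, so that its fall can come from the cardiomyocytes themselves. The endoderm list holds GATA4, which the heart also expresses. A second test then set epicardium against neural genes, and the difference of 1.13 had a 95% bootstrap interval from -0.11 to 2.34, which covers 0 and leaves a rise of all other types alike possible. A further test, added after that outcome was seen, found the other 7 lists to differ from each other (permutation of a Kruskal-Wallis statistic over 106 genes, p = 0.0096, and p = 0.0423 without smooth muscle). The tests point different ways on a rise of all other types alike, and a lower share of cardiomyocytes is not decided by them. More epicardial or fibroblast-like cells in the null cultures stays open, as does a change within cardiomyocytes, since whole cultures were measured.

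Among regions called in both contrasts, a choice that favours high ratios, 2110 higher and 328 lower ones had a ratio of heterozygous to null of at least 0.8, and those from 0.2 to 0.8 are called dose-ordered here. A peculiar level of the 2 WT libraries of the differential set could bring this about, since both contrasts share them. At these lower regions, peaks in both separate WT libraries were 3.27 percentage points more common (SE 1.90) than at dose-ordered ones of the same signal. That difference is not clear of 0, and it does not decide for the lower regions. At these higher regions the difference was -7.90 points (SE 1.25), opposite to what such WT libraries would give. This argues against them as what sets these higher regions apart from dose-ordered ones. Dose-ordered regions were called against the same WT libraries, so that an effect common to both classes cannot be seen. Some values go the other way, since these WT libraries had fewer peaks (61978) than the separate ones (78506), and 72.2% of all regions called higher in heterozygous libraries had a peak in both separate WT libraries against 62.1% of regions not called. For single regions such as those at ZNF559 and TAF9B a low level peculiar to these WT libraries stays open.

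The counts of RAD21 regions specific to a genotype were set against the other splits of the 6 libraries. With the genotype split itself there are 10 splits, too few for a share under 0.05. The genotype split gave 236 regions in WT and not heterozygous libraries (highest other split 1030), 487 in heterozygous and not WT (1030), 738 in WT and not null (798) and 336 in null and not WT (798). The number of splits with as many, the genotype split included, was 8, 2, 2 and 4 of 10. Each other split entered with the larger of its sides, which favours the other splits. With the same number of peaks from each library the counts were 271 and 329 (highest other split 313), and 627 and 443 (410). The number of splits with as many, counted in the same way, was 3, 1, 1 and 1 of 10. The split with 1030 regions set WT 1, WT 2 and heterozygous 2 against the rest and the one with 798 set WT 1, WT 2 and null 1 against the rest, which puts the libraries with the most peaks of each genotype together. This points to a structure by peak number in the other splits, which fell with equal peak numbers, while the count for WT and not null libraries fell less, from 738 to 627.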

How the results depend on the processing

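Alternatives for the gene lists near gene ends, for calls with p-values adjusted over all regions, for stricter calls at TBX5 and for H3K27ac peaks without each replicate were chosen after seeing the data, and the others before. Of the alternatives tried, 91 gave the same direction and side of the threshold or a count within 1.5 times. Some could not do otherwise. For 29 moved, 4 reversed, 2 stronger and 1 weaker, causes were untested unless stated. At an adjusted p under 0.01 the heterozygous calls fell to 760 lower and 1818 higher regions and those shared by both contrasts to 2413, and at a log2 fold change of 1 to 996 and 2226, since fewer regions can pass. Above the median signal, with fewer regions tested, null calls were 10935 lower and 9750 higher. The dose ratio was 0.41 at a log2 fold change of 1, 0.42 at an adjusted p under 0.01, 0.41 after centring and 0.46 above the median signal. The null excess of H3K27ac peaks was 6750 for strict peaks and between 8813 and 23747 without a replicate. The heterozygous minus WT difference in RAD21 peaks turned to -313 at a -log10 q of 5 and to -1629 at a fold enrichment of 4. The Jaccard difference passed with a replicate block (exact permutation p = 0.0278) and with equal peak numbers (difference 0.0162). With replicate block pairing the occupancy differences had exact sign-flip p-values of 0.25, 0.25, 0.5 and 0.25, the smallest possible being 0.25. At a -log10 q of 5 the RAD21 regions numbered 117 for WT and not heterozygous, 157 for heterozygous and not WT, and 111 for null and not WT. Without a replicate, with 2 libraries a genotype, they ranged from 706 to 2150, 1204 to 2345, 1079 to 1358, and for WT and not null from 1656 to 4824. The odds ratio of RAD21 at regions lower in null turned to 0.947 for RAD21 in 3 of 3 libraries and to 0.912 at the same width, these regions being wider than those not called. Of the list medians 27 passed with genes within 20 kb and 28 with regions near gene ends, but the heterozygous median of ventricular genes passed in neither (permutation with adjusted p 0.0792 and 0.538) and the congenital heart disease medians not near gene ends (0.114 in heterozygous, 0.0687 in null). Near gene ends the endoderm medians turned to -0.68 in heterozygous and -1.22 in null, and both passed (permutation with adjusted p 0.0272 and 0.0228). Null medians that passed only in alternatives were endothelium (0.0447) and WNT, BMP, NOTCH and TGF-beta genes (0.0195, median 0.25) within 20 kb, neural (0.0256, median 0.51) and early response genes (0.013) near gene ends, and smooth muscle (0.0394 and 0.0256) and hypoxia genes (0.0195 and 0.0256) in both. Heterozygous medians that did so within 20 kb were endothelium (0.0196) and endoderm (0.0032), the latter at 0.39, opposite in sign to its value near gene ends. Near gene ends they were also endothelium (0.0117), neural (0.0034), early response (0.0102) and skeletal muscle genes (0.00096, median -0.90). Of the gene counts, 3 were lost and 3 gained within 20 kb, and 7 were lost and 11 gained near gene ends (permutation, adjusted p in parentheses). Lost within 20 kb were atrial genes lower in null (0.072). Lost near gene ends were atrial, conduction and fatty acid genes lower in heterozygous libraries (0.0789, 0.365 and 0.142). So were fibroblast genes less often lower (0.936) and sarcomere genes less often higher (0.532) in null. Lost in both settings were sarcomere and conduction genes less often higher in heterozygous libraries (0.111 and 0.13 within 20 kb, 1 each near ends). Gained within 20 kb were cardiac transcription factors lower (0.037), endothelium higher (0.0469) and hypoxia genes less often higher (0.00576) in null. Gained near gene ends were, in null, cardiac transcription factors and conduction (0.0032 each), ventricular and congenital heart disease (0.0436 each), hypoxia (0.0048) and skeletal muscle genes (0.0494) lower, and epicardial (0.0032) and endothelial genes (0.0494) higher, and in heterozygous libraries congenital heart disease (0.0346) and skeletal muscle genes (0.0368) lower. The ribosomal reference list also passed there, with fewer genes lower than in random lists (0.0494), so that counts near gene ends are weak evidence. Centring gave 1937 lower and 5662 higher heterozygous calls. With genes of all kinds, the lower share of null-lower regions near gene ends (-0.374 points) no longer passed. Alternatives that need counts per library and those on motifs were not run. Depth per library was not analysed here, so its limit on weak peaks is unknown.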

Other observations

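The test of RAD21 at the block from SFXN3 to FBXW4 and the test of RAD21 at lost H3K27ac regions were chosen before their results were seen, and the bounds of the block were taken from the data. RAD21 regions that set WT and null libraries apart often lay where H3K27ac changed in the same direction, and those of heterozygous libraries were not tested. Among RAD21 regions that overlap a tested H3K27ac region, 63.0% of the 403 found in every WT and no null library overlapped a region lower in null, against 28.8% of the others (Fisher's exact test, odds ratio 4.21, p = 2.91e-45), and 2.73% overlapped a region higher in null. Of the 164 found in every null and no WT library, 63.4% overlapped a region higher in null, against 17.1% of the others (Fisher's exact test, odds ratio 8.39, p = 1.98e-39). The 2 assays were done on separate libraries, so that a shared gain or loss of cohesin and H3K27ac at these sites is a hypothesis that fits both, although neighbouring regions are not independent.

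A few regions stood apart from the dose order. Regions at ZNF559 and TAF9B had no peak in either WT library of the differential set and a peak in both heterozygous, both null and both separate WT libraries. The region at ZNF880 had a peak in both WT and both separate WT libraries and in no heterozygous or null library.

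Heterozygous libraries had lower H3K27ac along a block of 0.649 Mb of 10q24 from SFXN3 to FBXW4 (chromosome 10, 101042160 to 101691517), which also holds BTRC and POLL. Of 27 tested regions there 15 were called lower and 0 higher in heterozygous libraries and 11 lower in null libraries, with a heterozygous median log2 fold change of -1.19, against -0.28 over 43 regions within 500 kb on either side, and the null medians were -0.41 and -0.43. Loss of 1 copy may give such a block. RAD21 fold enrichment at 13 regions found in every library there differed by -0.26 (log2, heterozygous against WT, relative to the genome, 95% bootstrap interval -0.31 to -0.01), which lies above the bound of -0.3 set in advance against a lost copy while the interval reaches below it, and since fold enrichment is relative to a background that a lost copy would lower as well, this cannot decide.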
